A study of Homo sapiens with 21 samples.

How the data were processed

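Total RNA was extracted from NLF cells and sequenced with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols. The 21 samples form 7 groups of 3, grouped by line and treatment as the labels give them. Treatment began 24 h after plating and lasted 72 h with 20 nM trametinib or with DMSO, per the labels' protocols. That text is the same for all samples, while the series text names the treatment for the sgCON and knockout lines, so the culture time of the parental samples is uncertain. The DMSO concentration is given as 0.01% in the sample labels and 0.1% in the series text. The parental samples were mapped to the columns headed only with DMSO and a replicate number, which no other sample claims. Nothing in the labels says that the 3 replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

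The authors deposited FPKM values in 2 tables of 57820 genes by 21 samples. Per the submitters' processing notes, reads were aligned to hg19 with STAR 2.4.2 and quantified with RSEM 1.3.0. Whether the quantification used the strand of the reads is not known here, so antisense genes are uncertain. The calibrated table was checked to be the other table times 1 factor per library (0.927 to 1.07), with a largest relative deviation of 9.09e-15. FPKM carry no counts, so no counting interval is given.

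The gene IDs carried symbols in the tables; 5378 symbols were Ensembl IDs and 1231 rows shared a symbol with another. The gene type was found in GENCODE v29 (GRCh38) for 52338 gene IDs, of which 19263 are protein-coding. The same annotation gave transcript GC content for 15615 (96.4%) of the tested genes. Guide sequences were matched exactly to the YAP1 transcripts of that annotation with their PAM, so their positions are in GRCh38 and no hg19 coordinate is used. The scrambled guide had 0 exact matches among the transcripts. Small nuclear, small nucleolar and other short non-coding RNA genes took 19.4% to 36.4% of the FPKM of a library, and protein-coding genes 29.9% to 60.5%.

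Each library was divided by its median ratio to the gene-wise geometric mean. Genes with an FPKM of at least 1 in at least 3 libraries were kept (16194, of which 12192 are protein-coding). The value log2(FPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 21 libraries and eBayes with a trend. The pseudocount of 0.5 understates the change of genes with low values. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 11 comparisons were each knockout line against sgCON in DMSO and in trametinib, trametinib against DMSO in each line, the difference of the trametinib response of each knockout line from that of sgCON, sgCON against parental cells, and YAPKO2 against YAPKO1 in DMSO.

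The 25 gene lists were fixed with the comparisons, the thresholds and the settings before the data were examined. They are the YAP/TAZ-TEAD target, Hippo pathway, MEK/ERK output, E2F target, mitosis, MYC/MYCN target, adrenergic and mesenchymal neuroblastoma, neuronal differentiation, BCL2 family, p53 target, interferon response, extracellular matrix and adhesion, receptor tyrosine kinase, cholesterol synthesis, ATF4 and unfolded protein response, glycolysis and hypoxia, lysosome and autophagy, cytosolic ribosomal protein, mitochondrially encoded, replication-dependent histone, Schwann cell, fibroblast, epithelial, and blood and endothelial marker genes. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with an estimated correlation. Of 275 tests 121 were called, and 48 of those hold with an estimated correlation. Some of these lists share genes, such as POSTN and BBC3. MYCN is itself a member of the MYC/MYCN target list.

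Named genes followed a rule fixed in advance. YAP1 came first. Among readable, mostly protein-coding symbols with an adjusted p under 0.05 and no overlap between the 3 and 3 values (which chance gives for 10% of genes), the rule took the 10 largest rises and falls with trametinib in sgCON. It took the 10 rises and 10 falls shared by both knockout lines in DMSO, ranked by the smaller change, and 5 and 5 for the trametinib comparison, for the response difference and for sgCON against parental cells. The criterion of no overlap was not applied to the response difference, which involves 4 groups. Up to 4 members with the largest absolute change were taken from each list described. MYCN and CCND1 levels, and comparisons with parental cells, were chosen after their values were seen.

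The alternatives were pseudocounts of 0.1 and 1, no filter, no scaling, quantile normalization, the calibrated table, only the groups compared, a 2-fold threshold, a replicate block, and leaving out each replicate. Added after seeing the data were a spline correction for transcript GC content (5 degrees of freedom), the same with the replicate block, and leaving out the 2 libraries whose GC trend lay furthest above the other replicates of their groups (YAPKO1 DMSO replicate 3 and YAPKO2 trametinib replicate 2). Same-numbered replicates did not deviate together: 0 of 21 pairs of groups had every such correlation over 0.1, so the number was not treated as a pairing. The shared sgCON libraries were simulated 100 times with unchanged groups, and, after seeing the data, also split 1 and 2 between the knockout lines in 6 ways.

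The scripts were tested on simulated data. For trametinib in sgCON, over 14992 genes, 83% of 100 genes changed by 1 (log2) and 97% of 100 changed by 2 were recovered, with 11 false calls among 191. The changed genes were drawn from those with a mean log2 value over 1 in sgCON in DMSO. All groups otherwise had the same means, and the noise was independent between genes and held no GC trend. These rates therefore do not carry over to the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Cell line data only were used, and no group was defined from the values. Some genes are not reported here.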

Results

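Gene expression was measured by RNA sequencing of total RNA in NLF, a human neuroblastoma cell line, and in lines made from it. The 21 libraries form 7 groups of 3. They are the parental line, a control line with Cas9 and a scrambled guide (sgCON), and 2 YAP1 knockout lines (YAPKO1 and YAPKO2). Each of the last 3 lines was grown with trametinib, an inhibitor of the MEK kinases, at 20 nM for 72 h, or with its solvent DMSO. YAP1 encodes a transcriptional coactivator that the Hippo pathway restrains, and the series concerns YAP and resistance to trametinib. Values are FPKM scaled between libraries, given as mean ± SD with n = 3, and changes are log2 ± SE from limma over 16194 genes. The tables hold FPKM, so the number of reads is unknown. Depth relative to a parental library, estimated from the ratios of low values, ran from 0.768 to 1.67. Each library had between 13728 and 14425 genes at an FPKM of 1 or more. The 10 genes with the highest FPKM took 29.6% to 59.2% of the FPKM of a library.

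Libraries differed in how strongly GC-rich genes were represented. The GC trend of a library is the median deviation from the gene means of GC-rich genes minus that of GC-poor genes. These are the protein-coding genes in the top (57.6% GC or more) and bottom (43.4% or less) quartiles of transcript GC content. The trend ran from -0.59 (log2) in a parental library to 1.33 in YAPKO2 trametinib replicate 2. YAPKO1 DMSO replicate 3 also stood apart from the other replicates of its group (0.67), and so did YAPKO2 DMSO replicate 2 (0.59). YAPKO2 trametinib replicate 3 (-0.24) and YAPKO1 trametinib replicate 2 (-0.07) lay below the others of their groups. Across genes, which are not independent replicates, the log2 change correlated with transcript GC content by a Spearman rho of 0.341 for YAPKO1 and 0.431 for YAPKO2 against sgCON in DMSO. In trametinib the rho was 0.350 and 0.424. For trametinib against DMSO it was 0.254 in sgCON, 0.259 in YAPKO1 and 0.227 in YAPKO2.

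**Figure D1:**
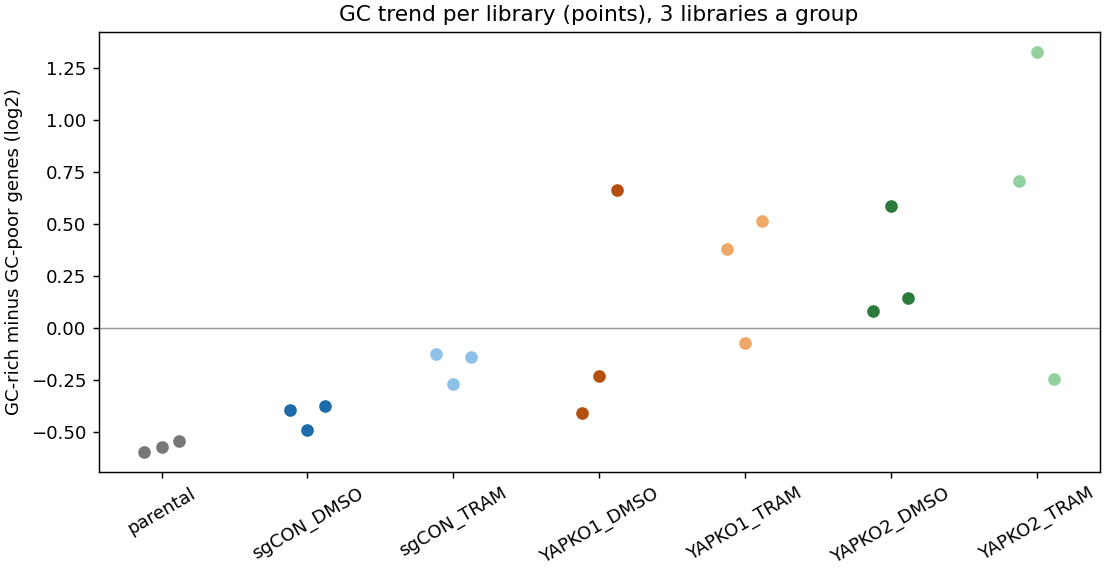
GC trend in each of the 21 libraries (points, 3 a group), as the median log2 deviation of GC-rich genes minus that of GC-poor genes. The highest library, at 1.33, is YAPKO2 trametinib replicate 2, and the parental libraries are the lowest, down to -0.59.

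YAP1 RNA (ENSG00000137693.9) was lowered in both knockout lines but not absent. It stood at 25.6 ± 1.88 in sgCON, 11.7 ± 2.30 in YAPKO1 and 2.89 ± 0.256 in YAPKO2 in DMSO. In trametinib it was 23.3 ± 1.05, 11.5 ± 1.22 and 2.54 ± 1.29. Parental cells held 31.9 ± 2.17. The log2 change against sgCON in DMSO was -1.11 ± 0.23 in YAPKO1 (limma adjusted p = 0.00385) and -2.94 ± 0.23 in YAPKO2 (adjusted p = 5.32e-08), and every YAPKO library lay below every sgCON library. Trametinib gave no called change of YAP1 in sgCON (-0.13 ± 0.23). The YAPKO1 guide CGCCGTCATGAACCCCAAGA matched chromosome 11 at 102111058 to 102111077 (GRCh38), in the coding part of exon 1 of 7 of the 11 annotated YAP1 transcripts. The YAPKO2 guide GTGCACGATCTGATGCCCGG matched 102110997 to 102111016 in the same exon, on the opposite strand. A small deletion or insertion at such a site need not change the RNA level, so these values describe RNA and not protein.

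**Figure D2:**
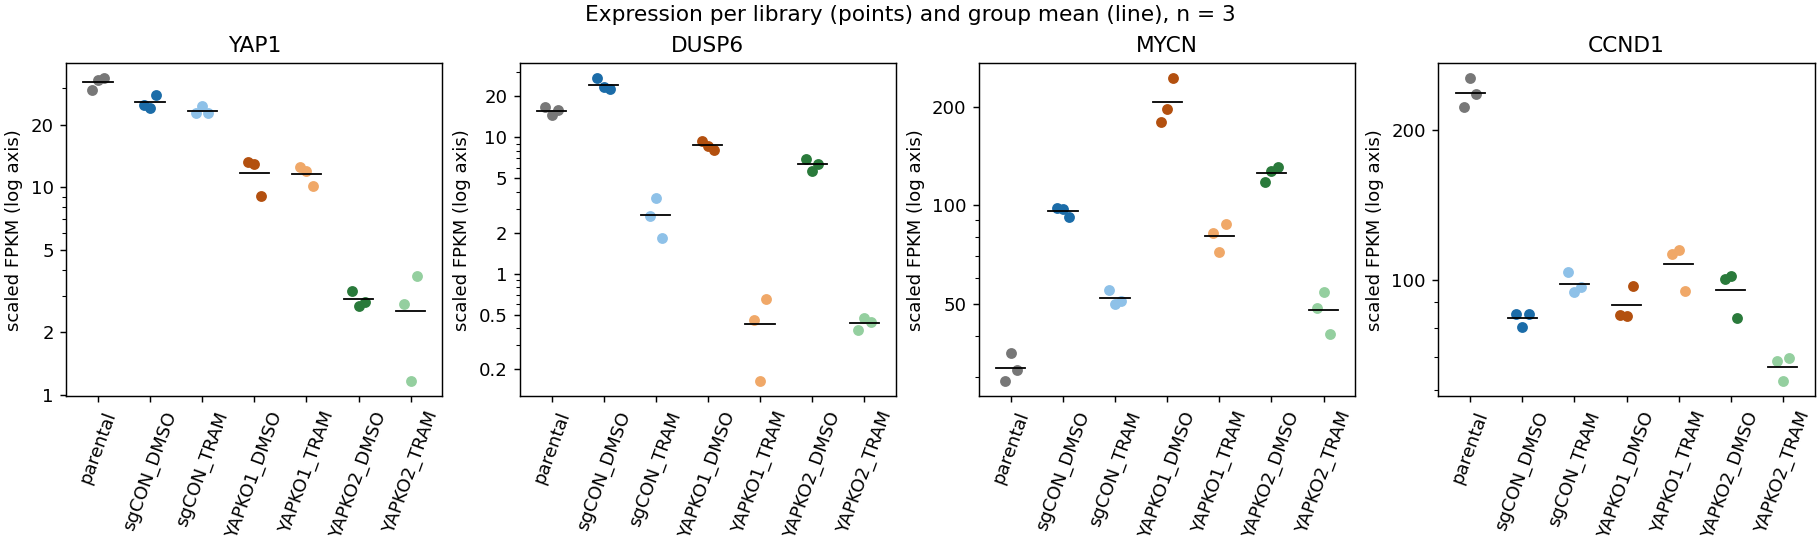
Scaled FPKM of YAP1, DUSP6, MYCN and CCND1 in each library (points, log axis), with the mean of each group of 3 as a line. YAP1 is lowest in the YAPKO2 groups (2.89 in DMSO), and DUSP6 falls with trametinib in each of the lines. CCND1, a member of the MEK/ERK output list, lay higher with trametinib in sgCON (94.3 to 103.5, against 80.3 to 85.3 in DMSO). Its ranges overlapped in YAPKO1 (94.9 to 114.6 against 84.4 to 97.1), and it lay lower in YAPKO2 (62.5 to 69.5 against 83.6 to 101.6). MYCN and CCND1 were chosen for the plot after their values were seen.

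How trametinib acts in cells with intact YAP1 was addressed by comparing sgCON with and without the drug. ERK pathway output fell: the ETS transcription factors ETV4 and ETV5 dropped from 37.7 ± 3.75 to 1.83 ± 0.341 and from 20.8 ± 1.49 to 1.69 ± 0.669. DUSP6, the phosphatase that ERK signalling induces against itself, dropped from 24.4 ± 2.39 to 2.69 ± 0.863. The peptide and vesicle genes NPY, SCG2 and SYT4 also fell, by log2 changes of -2.91 ± 0.20, -2.56 ± 0.17 and -3.63 ± 0.28. Among the rises were the water channel AQP1 (2.36 ± 0.20), the nicotinic receptor subunit CHRNA3 (14.6 ± 2.34 to 49.4 ± 6.30) and the small GTPase RHOB (9.63 ± 0.533 to 33.4 ± 3.60).

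Of the MEK/ERK output genes, 0 of 21 measured members rose and 13 fell (1 and 16 adjusted over the list alone), with a median log2 change of -0.80 and a camera adjusted p of 7.19e-20 (adjusted p = 0.000189 with an estimated correlation). ETV4 had the lowest change (-4.04 ± 0.19, adjusted p = 5.58e-10), and the ERK feedback inhibitor SPRY4 fell by a log2 change of -1.97 ± 0.23. Of the adrenergic neuroblastoma genes, markers of the sympathetic-like state of these tumours, 8 of 25 measured members rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 change of 0.31 and a camera adjusted p of 9.03e-06 (adjusted p = 0.0231 with an estimated correlation). The noradrenaline transporter SLC6A2 (1.44 ± 0.16) and the transcription factor GATA2 (1.13 ± 0.14) rose, while the receptor tyrosine kinase RET fell (-2.17 ± 0.15). Of the extracellular matrix and adhesion genes, 0 of 24 measured members rose and 7 fell (1 and 10 adjusted over the list alone), with a median log2 change of -0.36 and a camera adjusted p of 9.03e-06 (adjusted p = 0.0213 with an estimated correlation), led by POSTN (-2.01 ± 0.34) and TGFBI (-1.77 ± 0.26). MYCN itself fell from 96.2 ± 3.48 to 52.1 ± 2.69 (-0.88 ± 0.12). The E2F target genes, which serve DNA replication, showed no called change: 1 of 51 measured members rose and 1 fell (1 and 1 adjusted over the list alone), with a median log2 change of 0.07 and a camera adjusted p of 0.251. The same held for the mitosis genes, where 1 of 40 measured members rose and 0 fell (1 and 0 adjusted over the list alone), with a median log2 change of -0.04 and a camera adjusted p of 0.74. Of the YAP/TAZ-TEAD target genes, 1 of 18 measured members rose and 2 fell (2 and 2 adjusted over the list alone), with a median log2 change of -0.14 and a camera adjusted p of 0.791.

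In all, 372 genes were higher and 465 lower with trametinib in sgCON, 837 together. Other top rises were SHD (2.16), PGAM2 (1.95), C11orf96 (1.85), KCTD16 (1.79), SPOCK3 (1.79), CADM2 (1.77) and ABCA12 (1.73). Other top falls were CHODL (-2.87), PRSS12 (-2.49), DOCK2 (-2.46) and PLCL1 (-2.45). The share of called genes that was higher was 44.4%, and 54.8% with the calibrated table. With only the groups compared the count is 2674. It is 479 without sgCON trametinib replicate 1, and between 488 and 546 without any other of the 6 libraries.

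**Figure D3:**
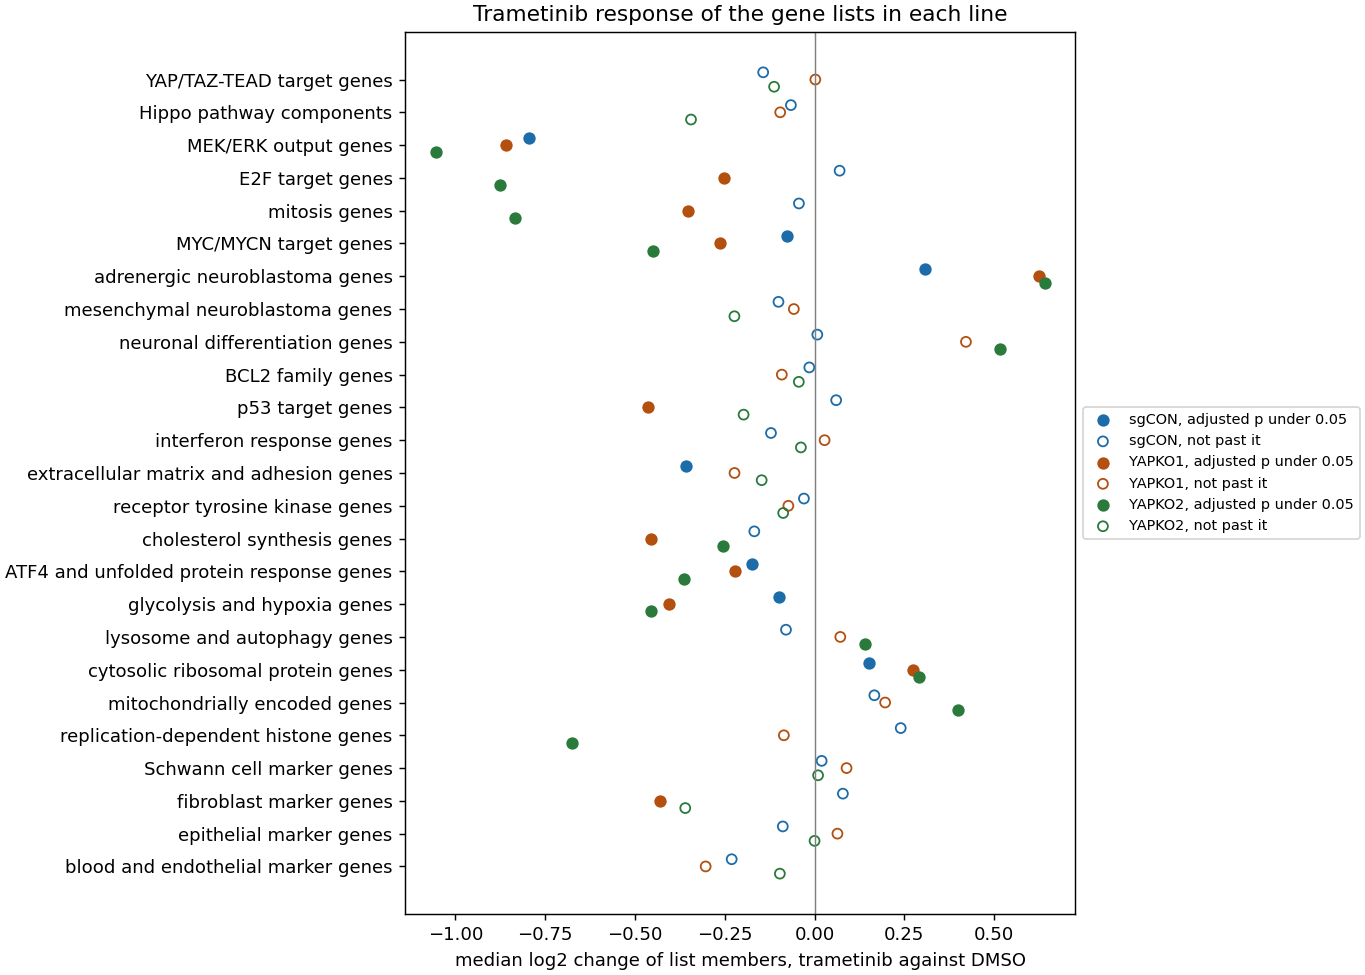
Median log2 change of the members of each of the 25 gene lists with trametinib in sgCON, YAPKO1 and YAPKO2, filled where the camera adjusted p was under 0.05. The MEK/ERK output genes lie at -0.80 to -1.05 in the lines, and the E2F target genes at 0.07 in sgCON and -0.88 in YAPKO2.

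Both knockout lines also answered trametinib with a fall of ERK output. ETV4 went from 43.3 ± 10.6 to 2.07 ± 0.538 in YAPKO1 and from 34.7 ± 5.23 to 0.374 ± 0.173 in YAPKO2. DUSP6 went from 8.74 ± 0.686 to 0.427 ± 0.248 in YAPKO1 and from 6.335 ± 0.674 to 0.436 ± 0.0463 in YAPKO2. Its level in DMSO was thus already below that of sgCON (24.4 ± 2.39), and the end levels lie under the pseudocount of 0.5. The sympathetic enzyme gene DBH rose by 2.11 ± 0.23 in YAPKO1 and 2.24 ± 0.23 in YAPKO2, and the secretory granule gene CHGA by 1.59 ± 0.25 and 3.79 ± 0.25. In YAPKO2 genes of DNA replication fell as well, among them MCM10 (-1.26 ± 0.16) and the replication checkpoint gene CLSPN (-1.24 ± 0.28).

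Of the MEK/ERK output genes in YAPKO1, 0 of 21 measured members rose and 16 fell (1 and 19 adjusted over the list alone), with a median log2 change of -0.86 and a camera adjusted p of 1.70e-26 (adjusted p = 3.63e-05 with an estimated correlation). In YAPKO2, 0 of 21 measured members rose and 16 fell (0 and 16 adjusted over the list alone), with a median log2 change of -1.05 and a camera adjusted p of 1.90e-16 (adjusted p = 0.000273 with an estimated correlation). Of the adrenergic genes, 14 of 25 measured members rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 0.63 and a camera adjusted p of 7.20e-13 (adjusted p = 0.000898 with an estimated correlation) in YAPKO1, and 16 of 25 measured members rose and 1 fell (18 and 3 adjusted over the list alone), with a median log2 change of 0.64 and a camera adjusted p of 3.47e-10 (adjusted p = 0.00172 with an estimated correlation) in YAPKO2. The E2F target genes went lower in both knockout lines. In YAPKO1, 0 of 51 measured members rose and 6 fell (0 and 9 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 2.59e-07 (adjusted p = 0.0126 with an estimated correlation). In YAPKO2, 0 of 51 measured members rose and 45 fell (0 and 49 adjusted over the list alone), with a median log2 change of -0.88 and a camera adjusted p of 1.47e-31 (adjusted p = 2.85e-05 with an estimated correlation). For the mitosis genes, 0 of 40 measured members rose and 6 fell (0 and 11 adjusted over the list alone), with a median log2 change of -0.35 and a camera adjusted p of 5.53e-07 (adjusted p = 0.0132 with an estimated correlation) in YAPKO1, where the mitotic kinase AURKA fell (-0.64 ± 0.08). In YAPKO2, 0 of 40 measured members rose and 30 fell (0 and 33 adjusted over the list alone), with a median log2 change of -0.84 and a camera adjusted p of 1.90e-18 (adjusted p = 0.000273 with an estimated correlation), with MAD2L1 of the spindle checkpoint at -1.44 ± 0.23. Of the MYC/MYCN target genes, 0 of 42 measured members rose and 8 fell (0 and 11 adjusted over the list alone), with a median log2 change of -0.26 and a camera adjusted p of 3.78e-08 (adjusted p = 0.0132 with an estimated correlation) in YAPKO1, and 0 of 42 measured members rose and 21 fell (0 and 23 adjusted over the list alone), with a median log2 change of -0.45 and a camera adjusted p of 2.76e-10 (adjusted p = 0.00648 with an estimated correlation) in YAPKO2. MYCN, itself a member of that list and counted among its falls, fell by a log2 change of -1.34 ± 0.12 and -1.39 ± 0.12. Of the cholesterol synthesis genes, 1 of 23 measured members rose and 6 fell (1 and 8 adjusted over the list alone), with a median log2 change of -0.45 and a camera adjusted p of 4.75e-05 (adjusted p = 0.00204 with an estimated correlation) in YAPKO1, and 1 of 23 measured members rose and 6 fell (1 and 6 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 0.00945 (adjusted p = 0.0261 with an estimated correlation) in YAPKO2.

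With trametinib 661 genes were higher and 614 lower in YAPKO1, and 1438 higher and 1804 lower in YAPKO2, 1275 and 3242 together. With only the groups compared the counts were 2674 in sgCON, 263 in YAPKO1 and 831 in YAPKO2, so the order of the lines by count depends on which libraries estimate the spread. Without scaling the share of higher calls was 62.3% in YAPKO1 (51.8% with it) and 56.4% in YAPKO2 (44.4% with it). The responses correlated across genes by r = 0.415 between sgCON and YAPKO1, 0.351 between sgCON and YAPKO2, and 0.508 between the knockout lines. The value between the knockout lines was 0.425 without YAPKO2 trametinib replicate 2. It was lower still without YAPKO1 DMSO replicate 3 as well, so the order of these correlations depends on the libraries used. YAPKO1 gave 752 genes without its DMSO replicate 2, 752 without its trametinib replicate 3, 819 without its trametinib replicate 1 and 830 without its DMSO replicate 1.

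What YAP1 loss changes without the drug was addressed by comparing each knockout line with sgCON in DMSO. S100A10, a partner of annexin A2, fell from 139.9 ± 9.07 to 5.93 ± 2.54 in YAPKO1 and 0.0635 ± 0.110 in YAPKO2. Annexin A1 (ANXA1) fell from 42.5 ± 2.03 to 1.97 and 0.119. The caveolar coat gene CAVIN1 and the matrix gene POSTN fell from 8.02 and 20.0 to 0.0468 and 0.504 in YAPKO1. The neurotrophin receptor NTRK3 rose from 0.788 ± 0.740 to 12.2 ± 3.90 and 15.2 ± 4.55, and the neurogenic factor NEUROD1 from 0.332 ± 0.109 to 7.79 ± 2.20 and 12.4 ± 2.71. The cell surface proteoglycan SDC2 rose from 0.678 ± 0.298 to 52.4 ± 9.19 and 11.6 ± 1.47.

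Of the extracellular matrix and adhesion genes, 1 of 24 measured members rose and 9 fell (1 and 12 adjusted over the list alone), with a median log2 change of -0.58 and a camera adjusted p of 3.41e-07 (adjusted p = 0.00773 with an estimated correlation) in YAPKO1. In YAPKO2, 2 of 24 measured members rose and 13 fell (2 and 15 adjusted over the list alone), with a median log2 change of -0.72 and a camera adjusted p of 1.90e-06 (adjusted p = 0.00892 with an estimated correlation). Fibrillin (FBN1) stood at -1.12 ± 0.17 and -2.61 ± 0.17, and POSTN at -4.39 ± 0.34 and -3.61 ± 0.34. Of the YAP/TAZ-TEAD target genes, 0 of 18 measured members rose and 6 fell (0 and 6 adjusted over the list alone), with a median log2 change of -0.28 and a camera adjusted p of 0.00507 (adjusted p = 0.155 with an estimated correlation) in YAPKO1. In YAPKO2, 3 of 18 measured members rose and 10 fell (3 and 10 adjusted over the list alone), with a median log2 change of -0.45 and a camera adjusted p of 0.00636 (adjusted p = 0.115 with an estimated correlation), a call lost with only the groups compared. CYR61, a standard reporter of YAP activity, was low in sgCON (1.87). It changed by -0.71 ± 0.23 in YAPKO1 and -1.48 ± 0.23 in YAPKO2. The YAPKO1 call was lost without any 1 of the 6 libraries other than YAPKO1 DMSO replicate 3. In parental libraries CYR61 lay between 4.14 and 5.36, above the 1.6 to 2.1 of the sgCON libraries in DMSO. CTGF, of the same list, was also higher in parental libraries (1.8 to 2.4) than in sgCON (0.28 to 0.92). CRIM1 had the largest change of that list (-3.09 ± 0.36 and -2.84 ± 0.36), but it was also low in parental cells, at 0.739 ± 0.252. In YAPKO2 the kinase gene NUAK2, a member of the same list, rose by 1.56 ± 0.18.

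The p53 target genes were lower in both lines than in sgCON. In YAPKO1, 0 of 21 measured members rose and 7 fell (0 and 13 adjusted over the list alone), with a median log2 change of -0.47 and a camera adjusted p of 6.30e-06 (adjusted p = 0.00773 with an estimated correlation). In YAPKO2, 0 of 21 measured members rose and 20 fell (0 and 20 adjusted over the list alone), with a median log2 change of -1.08 and a camera adjusted p of 4.31e-14 (adjusted p = 0.000124 with an estimated correlation). The cell cycle inhibitor CDKN1A went from 389 ± 9.83 to 164 ± 32.1 and 94.4 ± 5.95, and the stress cytokine GDF15 from 73.7 ± 2.67 to 35.8 ± 6.55 and 18.3 ± 2.50. In parental cells they stood at 124 ± 8.47 and 14.6 ± 2.79. Of the adrenergic genes, 10 of 25 measured members rose and 2 fell (11 and 2 adjusted over the list alone), with a median log2 change of 0.14 (0.22 without sgCON DMSO replicate 1) and a camera adjusted p of 0.000723 (adjusted p = 0.0879 with an estimated correlation) in YAPKO1, and 15 of 25 measured members rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 change of 0.70 and a camera adjusted p of 3.28e-08 (adjusted p = 0.00764 with an estimated correlation) in YAPKO2. HAND1, a factor of sympathetic development, rose by 2.98 ± 0.19 in YAPKO1. STMN2, of the same list, went opposite ways in the lines (-1.66 ± 0.19 and 1.11 ± 0.19). Of the mesenchymal genes, 2 of 22 measured members rose and 7 fell (2 and 7 adjusted over the list alone), with a median log2 change of -0.30 and a camera adjusted p of 0.0146 (adjusted p = 0.227 with an estimated correlation) in YAPKO2, a call also lost with only the groups compared, while the call was not reached in YAPKO1, where 4 of 22 measured members rose and 4 fell (4 and 5 adjusted over the list alone), with a median log2 change of -0.21 and a camera adjusted p of 0.147. MYCN was higher in both knockout lines, by 1.09 ± 0.12 and 0.38 ± 0.12.

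In YAPKO1 1024 genes were higher and 923 lower, and in YAPKO2 2292 and 2081. The lines shared 754 higher and 651 lower genes, and 29 went opposite ways. Independent lists of those sizes would share 144.9 and 118.6. Changes correlated across genes by r = 0.716, where the shared controls alone gave 0.50. The covariance was 0.273 against 0.0525 simulated, a difference of 0.221. With the sgCON libraries split 1 and 2 between the lines, so that none was in both changes, the covariance was 0.221 to 0.233 over 6 splits (r = 0.492 to 0.547). Both lines are still set against the same control line. The simulation held no GC trend, whereas the changes of both lines correlated with GC content (Spearman rho 0.341 and 0.431). What that trend adds to the covariance was not measured, and splitting the controls does not remove it. Of the 754 shared rises 396 were also higher than in parental cells in both lines, and of the 651 shared falls 396 were lower in both. For 216 of the rises and 138 of the falls, sgCON itself differed from parental cells in the opposite direction. Other shared rises were ATRNL1 (3.69 and 4.13), ADCYAP1R1 (3.55 and 3.69), CITED1 (3.42 and 3.57), IGFBPL1 (3.12 and 3.69) and NEK9 (3.23 and 3.56). AC008878.1 rose by 3.00 and 2.90, with calls lost without sgCON DMSO replicate 1 or 2, YAPKO1 DMSO replicate 2 or 3, or YAPKO2 DMSO replicate 3, and was at 3.96 ± 3.79 in parental cells against 0.329 ± 0.569 in sgCON. NEK9 was at 0.370 ± 0.141 in sgCON and 8.22 ± 0.693 in parental cells, so its level in the knockout lines (7.67 ± 1.53 and 9.70 ± 0.785) was near the parental level. Other shared falls were CD36 (-3.63 and -4.97), MOXD1 (-2.87 and -5.96), SLCO2B1 (-2.63 and -3.07) and KRT18 (-2.58 and -3.72). KRT18 was at 2.85 ± 0.294 in parental cells and 14.9 ± 0.712 in sgCON, and against parental cells it changed by -0.38 ± 0.21 (adjusted p = 0.189) in YAPKO1 and -1.52 ± 0.21 in YAPKO2. FAM183A was listed at 0 in both knockout lines. Each guide is represented by 1 line, so a difference between lines is not separated here from an effect of the knockout. There were 821 genes in YAPKO1 and 6170 in YAPKO2 with only the groups compared. The YAPKO1 count falls to 1205 without sgCON DMSO replicate 3, and the YAPKO2 count to 2599 without YAPKO2 DMSO replicate 2. Without YAPKO1 DMSO replicate 3 the correlation was 0.597.

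The same comparison under trametinib asks what separates the lines while MEK is inhibited. S100A10 and ANXA1 stayed low, at 1.33 and 0.15 in YAPKO1 against 75.3 ± 8.27 and 9.41 ± 2.83 in sgCON. SDC2 was at 69.6 ± 1.49 in YAPKO1 and 13.4 ± 1.16 in YAPKO2 against 0.606 ± 0.171 in sgCON. The receptor ADCYAP1R1 rose by 3.89 ± 0.25 and 4.47 ± 0.25, and FAM163A by 3.47 and 4.52. NEK9 differed by 3.81 and 3.97, KRT18 by -3.66 and -4.31, CAVIN1 by -3.55 and -3.55, and MOXD1 by -3.22 and -5.33.

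Of the p53 target genes, 0 of 21 measured members rose and 18 fell (0 and 19 adjusted over the list alone), with a median log2 change of -0.97 and a camera adjusted p of 3.04e-16 (adjusted p = 5.50e-05 with an estimated correlation) in YAPKO1, and 0 of 21 measured members rose and 20 fell (0 and 20 adjusted over the list alone), with a median log2 change of -1.29 and a camera adjusted p of 1.03e-13 (adjusted p = 8.80e-05 with an estimated correlation) in YAPKO2. GDF15 differed by -2.11 ± 0.22 and -2.90 ± 0.22. The E2F target genes were lower in both lines under trametinib. In YAPKO1, 0 of 51 measured members rose and 11 fell (0 and 14 adjusted over the list alone), with a median log2 change of -0.15 and a camera adjusted p of 0.000118 (adjusted p = 0.05 with an estimated correlation). In YAPKO2, 0 of 51 measured members rose and 47 fell (0 and 48 adjusted over the list alone), with a median log2 change of -0.87 and a camera adjusted p of 1.71e-23 (adjusted p = 8.80e-05 with an estimated correlation), with cyclin E2 (CCNE2) at -2.21 ± 0.43. For the mitosis genes, 0 of 40 measured members rose and 7 fell (0 and 16 adjusted over the list alone), with a median log2 change of -0.35 and a camera adjusted p of 2.28e-07 (adjusted p = 0.0219 with an estimated correlation) in YAPKO1, and 0 of 40 measured members rose and 32 fell (0 and 36 adjusted over the list alone), with a median log2 change of -1.04 and a camera adjusted p of 1.03e-13 (adjusted p = 0.00111 with an estimated correlation) in YAPKO2. Of the adrenergic genes, 12 of 25 measured members rose and 1 fell (14 and 2 adjusted over the list alone), with a median log2 change of 0.40 and a camera adjusted p of 1.09e-07 (adjusted p = 0.0101 with an estimated correlation) in YAPKO1, and 19 of 25 measured members rose and 1 fell (19 and 2 adjusted over the list alone), with a median log2 change of 0.80 and a camera adjusted p of 4.96e-11 (adjusted p = 0.00111 with an estimated correlation) in YAPKO2. The kinase gene ALK, of that list, went from 0.106 ± 0.0257 in sgCON to 1.99 ± 0.400 and 8.75 ± 0.709. Neuronal differentiation genes were higher too: 10 of 23 measured members rose and 5 fell (11 and 5 adjusted over the list alone), with a median log2 change of 0.48 and a camera adjusted p of 0.00782 (adjusted p = 0.0353 with an estimated correlation) in YAPKO1, and 13 of 23 measured members rose and 6 fell (13 and 6 adjusted over the list alone), with a median log2 change of 1.19 and a camera adjusted p of 0.0015 (adjusted p = 0.00872 with an estimated correlation) in YAPKO2. Of the MEK/ERK output genes, 2 of 21 measured members rose and 7 fell (2 and 9 adjusted over the list alone), with a median log2 change of -0.27 (-0.16 without YAPKO1 trametinib replicate 2) and a camera adjusted p of 0.00172 (adjusted p = 0.0729 with an estimated correlation) in YAPKO1, and 2 of 21 measured members rose and 11 fell (2 and 12 adjusted over the list alone), with a median log2 change of -0.55 and a camera adjusted p of 0.000287 (adjusted p = 0.0495 with an estimated correlation) in YAPKO2. Of the YAP/TAZ-TEAD target genes, 1 of 18 measured members rose and 5 fell (1 and 5 adjusted over the list alone), with a median log2 change of -0.26 (-0.16 without sgCON trametinib replicate 3) and a camera adjusted p of 0.0117 (adjusted p = 0.129 with an estimated correlation) in YAPKO1, and 3 of 18 measured members rose and 10 fell (3 and 11 adjusted over the list alone), with a median log2 change of -0.59 and a camera adjusted p of 0.0139 (adjusted p = 0.116 with an estimated correlation) in YAPKO2.

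Under trametinib 1279 genes were higher and 1135 lower in YAPKO1, and 2903 and 2970 in YAPKO2. They shared 953 higher and 881 lower genes, with 50 opposite, where independent lists would share 229.3 and 208.2. The correlation was 0.715 (0.499 simulated) and the covariance 0.310 (0.0523 simulated, a difference of 0.258). With the controls split the covariance was 0.247 to 0.265. Neither the simulation nor this split accounts for the GC trend. With only the groups compared there were 3566 genes in YAPKO1 and 2789 in YAPKO2, the opposite order. Leaving out YAPKO1 trametinib replicate 3 gave 1419 genes in YAPKO1, leaving out its replicate 1 gave 1604, and leaving out sgCON trametinib replicates 1 or 2 gave 1579 or 1507.

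Whether YAP1 loss alters the response to trametinib was tested as the difference between the response of each knockout line and that of sgCON. Decorin (DCN), a matrix proteoglycan, rose with trametinib in sgCON (13.9 ± 1.89 to 30.6 ± 0.702) and fell in YAPKO1 (12.5 ± 1.82 to 4.48 ± 1.33) and YAPKO2 (209 ± 9.81 to 124 ± 5.49). AURKA went from 43.5 ± 1.52 to 41.2 ± 1.12 in sgCON, from 50.0 ± 1.47 to 31.8 ± 2.16 in YAPKO1 and from 49.3 ± 1.92 to 23.4 ± 0.696 in YAPKO2. The kinase gene PRKCA fell in each line, from 41.8 to 29.7, from 30.5 to 15.1 and from 31.1 to 10.1. SCUBE1, a secreted and membrane-bound glycoprotein, went from 1.07 ± 0.268 to 6.64 ± 0.683 in YAPKO1 and from 3.54 ± 0.798 to 17.2 ± 3.31 in YAPKO2, against 0.756 ± 0.402 to 0.966 ± 0.197 in sgCON. METTL27 fell in sgCON (-0.86 ± 0.17) and rose in YAPKO1 (0.68 ± 0.17) and YAPKO2 (0.60 ± 0.17). When 1 library was left out, the YAPKO1 calls of AURKA and PRKCA were lost in 12 of 12 fits, and that of SCUBE1 in 11 of 12.

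**Figure D4:**
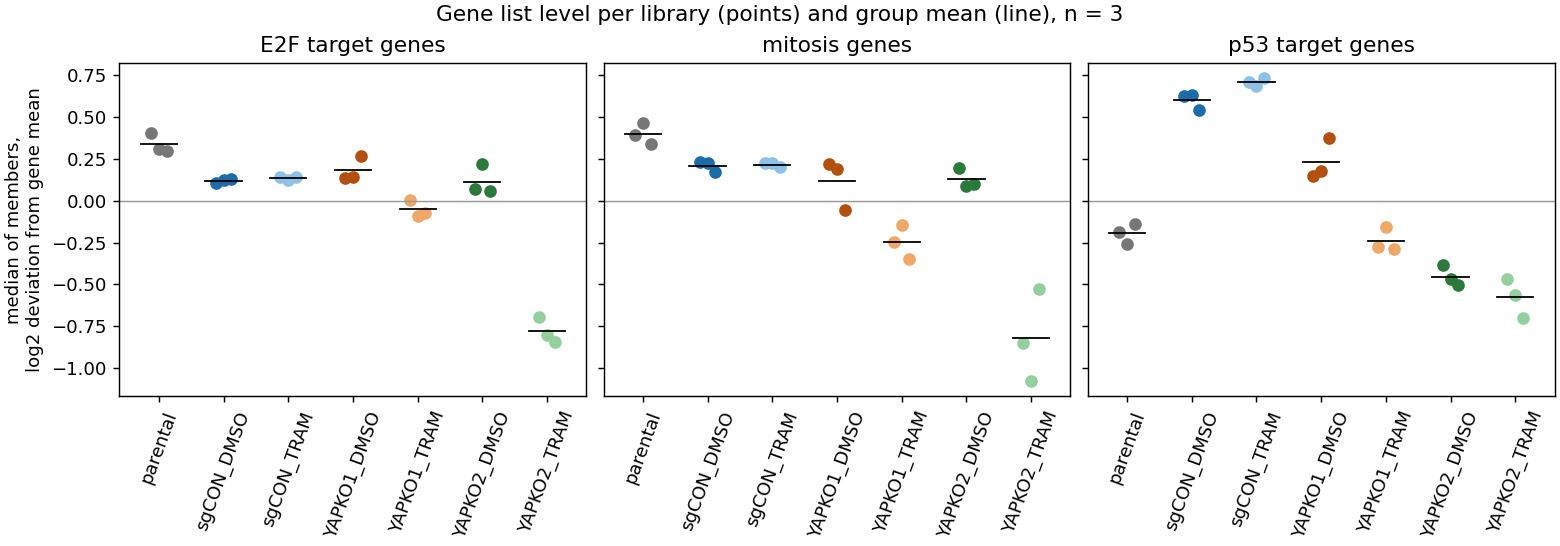
Median log2 deviation from the gene means of the E2F target, mitosis and p53 target genes in each library (points), with the mean of each group of 3 as a line. The 3 YAPKO2 libraries with trametinib are the lowest for the E2F target and mitosis genes, and the sgCON libraries are the highest for the p53 target genes.

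The response of the E2F target genes was lower in YAPKO2 than in sgCON, as 0 of 51 measured members rose and 33 fell (0 and 47 adjusted over the list alone), with a median log2 change of -0.93 and a camera adjusted p of 4.26e-43 (adjusted p = 4.30e-06 with an estimated correlation). RRM1, a subunit of the enzyme that makes deoxynucleotides, differed by -1.33 ± 0.16. For YAPKO1, 0 of 51 measured members rose and 0 fell (0 and 5 adjusted over the list alone), with a median log2 change of -0.30 and a camera adjusted p of 2.69e-12 (adjusted p = 0.00225 with an estimated correlation). Of the mitosis genes, 0 of 40 measured members rose and 21 fell (0 and 25 adjusted over the list alone), with a median log2 change of -0.91 and a camera adjusted p of 2.50e-23 (adjusted p = 0.000114 with an estimated correlation) in YAPKO2, and 0 of 40 measured members rose and 1 fell (0 and 2 adjusted over the list alone), with a median log2 change of -0.35 and a camera adjusted p of 4.06e-10 (adjusted p = 0.00547 with an estimated correlation) in YAPKO1. The mitotic regulator FOXM1 (-1.32 ± 0.21) and the centromere histone gene CENPA (-1.24 ± 0.17) differed in YAPKO2. Of the adrenergic genes, 6 of 25 measured members rose and 1 fell (8 and 2 adjusted over the list alone), with a median log2 change of 0.26 (0.17 without YAPKO2 trametinib replicate 2 and 0.13 without sgCON DMSO replicate 2) and a camera adjusted p of 0.000674 (adjusted p = 0.0645 with an estimated correlation) in YAPKO2, with CHGA at 2.89 ± 0.35 and ALK at 2.51 ± 0.22. In YAPKO1, 1 of 25 measured members rose and 0 fell (4 and 0 adjusted over the list alone), with a median log2 change of 0.25 and a camera adjusted p of 1.23e-05 (adjusted p = 0.0173 with an estimated correlation). Neuronal differentiation genes differed in YAPKO2: 8 of 23 measured members rose and 1 fell (9 and 2 adjusted over the list alone), with a median log2 change of 0.48 (0.23 without YAPKO2 trametinib replicate 3) and a camera adjusted p of 5.67e-05 (adjusted p = 0.00215 with an estimated correlation). Of these SYT4 (3.35 ± 0.40) was already at 0.558 ± 0.210 in YAPKO2 in DMSO, so it had little room to fall.

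The response differed for 32 genes upward and 8 downward in YAPKO1, and for 298 upward and 484 downward in YAPKO2. Shared were 22 higher and 5 lower genes, where independent lists would share 0.6 and 0.2. The differences correlated by r = 0.564 (0.50 simulated), with a covariance of 0.160, and both rest on the same sgCON libraries. The simulated covariance of 0.0525 held a single shared control group, whereas these differences share sgCON both in DMSO and in trametinib. That reference is therefore too low here, and how far the covariance exceeds what the shared controls give was not determined. SHISA3 (-1.82 and -1.14) and CBLN2 (-0.96 and -1.17) were among the shared falls. Leaving out 1 library ended the YAPKO2 call of SHISA3 in 5 of 12 fits and the YAPKO1 call of CBLN2 in 7 of 12. CPA4, SLCO2B1 and XIRP2 were shared rises, but in YAPKO2 in DMSO they stood at 0, 0 and 0.106, and could hardly fall further. The same holds for YAPKO1 in DMSO, where they stood at 0.0101, 0.198 and 0.229, under the pseudocount of 0.5. Their YAPKO1 calls were lost in 9 of 12, 11 of 12 and 7 of 9 such fits. The counts were 8 and 445 with only the groups compared. The YAPKO1 count was 12 without sgCON DMSO replicate 3, YAPKO1 trametinib replicate 1 or YAPKO1 trametinib replicate 3.

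How the control line differs from the line it was made from was addressed by comparing sgCON with parental cells in DMSO. The culture time of the parental samples is uncertain, so a difference in handling is not separated from making the line. MYCN, an oncogene that is amplified in a group of neuroblastomas, rose from 32.0 ± 3.19 to 96.2 ± 3.48. It is itself a member of the MYC/MYCN target list and is counted among the rises of that list. CDKN1A rose from 124 ± 8.47 to 389 ± 9.83 and GDF15 from 14.6 ± 2.79 to 73.7 ± 2.67. DCN fell from 98.8 ± 1.76 to 13.9 ± 1.89 and LRRC17 from 157 ± 2.86 to 17.5 ± 1.57. CCND1, the gene of cyclin D1, fell from 238 ± 15.7 to 83.6 ± 2.85. Of the p53 target genes, 16 of 21 measured members rose and 0 fell (18 and 1 adjusted over the list alone), with a median log2 change of 0.87 and a camera adjusted p of 1.34e-13 (adjusted p = 0.000151 with an estimated correlation), with BTG2, an antiproliferative gene, at 1.83 ± 0.13. Of the fibroblast marker genes, 1 of 9 measured members rose and 5 fell (1 and 5 adjusted over the list alone), with a median log2 change of -0.82 and a camera adjusted p of 0.000212 (adjusted p = 0.01 with an estimated correlation). Of the E2F target genes, 0 of 51 measured members rose and 12 fell (0 and 14 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 6.58e-05 (adjusted p = 0.0562 with an estimated correlation). Of the MYC/MYCN target genes, 5 of 42 measured members rose and 1 fell (7 and 1 adjusted over the list alone), with a median log2 change of 0.26 and a camera adjusted p of 0.000212 (adjusted p = 0.0909 with an estimated correlation). Of the extracellular matrix and adhesion genes, 1 of 24 measured members rose and 6 fell (1 and 8 adjusted over the list alone), with a median log2 change of -0.25 and a camera adjusted p of 0.00165 (adjusted p = 0.0579 with an estimated correlation). The largest rises were TMPRSS15 (4.06), HIST1H4C (3.14), ABCG1 (3.03), GLMP (2.61) and CRIM1 (2.60). The largest falls were NEK9 (-3.34), CPA4 (-3.31), LRRC17 (-3.14), GALC (-2.94) and KRT7 (-2.90). In all 1267 genes were higher and 1289 lower. The count was 4934 with only the groups compared, 1672 without parental replicate 3 and 1697 without sgCON DMSO replicate 2.

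The knockout lines themselves differed in DMSO. YAP1 was lower in YAPKO2 than in YAPKO1, by -1.83 ± 0.23. DCN was at 12.5 ± 1.82 in YAPKO1 and 209 ± 9.81 in YAPKO2. The sympathetic factor HAND1 was lower in YAPKO2 (-2.28 ± 0.19) and STMN2, a neuronal microtubule gene, higher (2.77 ± 0.19). Of the p53 target genes, 0 of 21 measured members rose and 12 fell (0 and 14 adjusted over the list alone), with a median log2 change of -0.59 and a camera adjusted p of 8.24e-13 (adjusted p = 0.000211 with an estimated correlation). Of the MEK/ERK output genes, 1 of 21 measured members rose and 5 fell (1 and 7 adjusted over the list alone), with a median log2 change of -0.31 (-0.20 without YAPKO1 DMSO replicate 3) and a camera adjusted p of 0.000529 (adjusted p = 0.0964 with an estimated correlation). Of the adrenergic genes, 8 of 25 measured members rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 change of 0.26 (0.43 without YAPKO1 DMSO replicate 3) and a camera adjusted p of 7.42e-05 (adjusted p = 0.0605 with an estimated correlation). In all 600 genes were higher and 525 lower in YAPKO2, and 382 genes were called with only the groups compared.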

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

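The results given first are those whose trametinib response differed between a knockout line and sgCON, by the test of the difference itself. The p53 target and MYCN patterns weighed at the end are differences in level, chosen after their values were seen. Chosen only after results were seen were the GC correction tests, the test of a raised sgCON level and the fit without 2 libraries, YAPKO1 DMSO replicate 3 and YAPKO2 trametinib replicate 2, whose GC trend lies furthest above the other replicates of their groups.

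The response differed for 40 genes in YAPKO1 and 782 in YAPKO2. Of 100 splits of the samples, 8 gave as many genes as YAPKO1 and 5 as many as YAPKO2, the real splits included, and the highest other splits gave 149 and 3432 genes. Each of the other splits with as many genes keeps or swaps all 6 labels of a line, so the drug response of that line stays in the count. These splits are therefore no measure of chance, which is left open for both counts. The split with 3432 genes swaps all 6 YAPKO2 labels, which turns the difference into a sum of responses, and so points to the structure of the samples. Splits that mix the labels of both lines gave at most 2 genes (83 splits for YAPKO1 and 84 for YAPKO2). In these the drug response adds to the spread within the mixed groups and lowers the count, so they do not measure chance either.

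In YAPKO1 the list medians that differed (log2) were MEK/ERK output -0.10, E2F target -0.30, mitosis -0.35, MYC/MYCN target -0.13, adrenergic 0.25, mesenchymal 0.23, neuronal differentiation 0.26, p53 target -0.50, extracellular matrix 0.23, cholesterol synthesis -0.19, glycolysis and hypoxia -0.21, lysosome 0.12, ribosomal protein 0.13, histone -0.34 and fibroblast marker genes -0.23. In YAPKO2 they were MEK/ERK output -0.29, E2F target -0.93, mitosis -0.91, MYC/MYCN target -0.32, adrenergic 0.26, neuronal differentiation 0.48, p53 target -0.18, extracellular matrix 0.50, ATF4 and unfolded protein response -0.13, lysosome 0.18, ribosomal protein 0.14 and histone genes -0.87.

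With an estimated correlation, calls were lost in YAPKO1 for the MEK/ERK (adjusted p = 0.0566), MYC/MYCN (0.0566), mesenchymal (0.262), neuronal (0.0566), extracellular matrix (0.0566), glycolysis (0.498), lysosome (0.364), ribosomal (0.483), histone (0.498) and fibroblast (0.0566) lists. In YAPKO2 they were lost for the MEK/ERK (adjusted p = 0.236), adrenergic (0.0645), p53 (0.204), ATF4 (0.427), lysosome (0.291), ribosomal (0.623) and histone (0.291) lists.

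Some calls were also lost when a library was left out, with the camera adjusted p then given in brackets. For YAPKO1 this holds for the mesenchymal list without YAPKO1 DMSO replicate 1 (0.0748), YAPKO1 DMSO replicate 2 (0.0546), YAPKO1 trametinib replicate 1 (0.0758), sgCON DMSO replicate 1 (0.0658), sgCON DMSO replicate 3 (0.103), sgCON trametinib replicate 1 (0.0745) or sgCON trametinib replicate 2 (0.1), the neuronal list without YAPKO1 DMSO replicate 3 (0.0923) or sgCON DMSO replicate 1 (0.0638), and the glycolysis list without YAPKO1 DMSO replicate 3 (0.597), YAPKO1 trametinib replicate 2 (0.16), sgCON DMSO replicate 1 (0.0638), sgCON DMSO replicate 2 (0.0727), sgCON trametinib replicate 1 (0.0672) or sgCON trametinib replicate 3 (0.137). It also holds for the fibroblast list without YAPKO1 DMSO replicate 3 (0.0567) or sgCON trametinib replicate 3 (0.0517), the lysosome list without YAPKO1 DMSO replicate 1 (0.0748) or YAPKO1 trametinib replicate 3 (0.0591), the ribosomal list without YAPKO1 DMSO replicate 1 (0.0515), and the histone list without YAPKO1 DMSO replicate 3 (0.597) or YAPKO1 trametinib replicate 2 (0.132). For YAPKO2 it holds for the MEK/ERK list without YAPKO2 DMSO replicate 2 (0.0754), YAPKO2 trametinib replicate 2 (0.0536), YAPKO2 trametinib replicate 3 (0.0686) or sgCON DMSO replicate 2 (0.0519), and the p53 list without YAPKO2 DMSO replicate 1 (0.093), YAPKO2 trametinib replicate 2 (0.0878), YAPKO2 trametinib replicate 3 (0.161), sgCON DMSO replicate 1 (0.0527), sgCON DMSO replicate 2 (0.0519), sgCON DMSO replicate 3 (0.0699), sgCON trametinib replicate 1 (0.0576) or sgCON trametinib replicate 3 (0.0649). The ATF4 list lost its call without YAPKO2 DMSO replicate 2 (0.118), YAPKO2 DMSO replicate 3 (0.0564), YAPKO2 trametinib replicate 1 (0.0684), YAPKO2 trametinib replicate 3 (0.328), sgCON DMSO replicate 1 (0.0536), sgCON DMSO replicate 2 (0.0519), sgCON trametinib replicate 1 (0.0625) or sgCON trametinib replicate 3 (0.0649), the ribosomal list without YAPKO2 DMSO replicate 1 (0.232) or YAPKO2 trametinib replicate 2 (0.532), and the lysosome list without YAPKO2 trametinib replicate 2 (0.051). With the GC correction the MEK/ERK call of YAPKO2 and the fibroblast call of YAPKO1 were lost. Without the 2 libraries named above, the MEK/ERK calls of both lines were lost, with those of the neuronal, glycolysis, histone and fibroblast lists in YAPKO1 and the p53, lysosome and ribosomal lists in YAPKO2.

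These list medians moved by over 1.5 times when a library was left out. In YAPKO1 the MEK/ERK median became -0.19 without YAPKO1 DMSO replicate 1, -0.24 without YAPKO1 trametinib replicate 1 and -0.06 without YAPKO1 trametinib replicate 3, the neuronal median 0.12 without YAPKO1 DMSO replicate 3, and the glycolysis median 0.00 without YAPKO1 DMSO replicate 3 and -0.12 without YAPKO1 trametinib replicate 2. The lysosome median became 0.25 without YAPKO1 DMSO replicate 3 and 0.19 without YAPKO1 trametinib replicate 2, the histone median -0.54 without YAPKO1 DMSO replicate 1, -0.07 without YAPKO1 DMSO replicate 3 and -0.20 without YAPKO1 trametinib replicate 2, and the fibroblast median -0.06 without YAPKO1 DMSO replicate 3 and -0.14 without YAPKO1 trametinib replicate 2. In YAPKO2 the MEK/ERK median became -0.45 without sgCON trametinib replicate 2, the adrenergic median 0.17 without YAPKO2 trametinib replicate 2 and 0.13 without sgCON DMSO replicate 2, and the neuronal median 0.23 without YAPKO2 trametinib replicate 3. The ATF4 median became -0.29 without YAPKO2 trametinib replicate 2 and 0.00 without YAPKO2 trametinib replicate 3, the lysosome median 0.32 without YAPKO2 trametinib replicate 3, the ribosomal median 0.06 without YAPKO2 DMSO replicate 1, 0.04 without YAPKO2 trametinib replicate 2 and 0.26 without YAPKO2 trametinib replicate 3, and the histone median -0.57 without YAPKO2 trametinib replicate 3.

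Genes that differed in both lines (YAPKO1 and YAPKO2) were SCUBE1 (1.94 and 1.88), CPA4 (1.81 and 1.84), SLCO2B1 (1.69 and 2.11), XIRP2 (1.48 and 1.74), METTL27 (1.54 and 1.46), DCN (-2.54 and -1.88), SHISA3 (-1.82 and -1.14), CBLN2 (-0.96 and -1.17), AURKA (-0.57 and -0.99) and PRKCA (-0.50 and -1.08). Leaving out each library in turn, AURKA and PRKCA lost the YAPKO1 call in 12 of 12 fits, SCUBE1 and SLCO2B1 in 11 of 12, CPA4 in 9 of 12, CBLN2 in 7 of 12 and XIRP2 in 7 of 9. SHISA3 lost the YAPKO2 call in 5 of 12. CPA4, SLCO2B1 and XIRP2 lay under the pseudocount of 0.5 in both knockout lines in DMSO, so they could hardly fall further there. With the GC correction the YAPKO1 calls of XIRP2 (1.48 ± 0.26 before and 1.48 ± 0.36 after, adjusted p = 0.0606) and AURKA (-0.57 ± 0.11 before and -0.57 ± 0.13 after, adjusted p = 0.0556) were lost, as the spread grew. YAPKO1 calls were also lost with a pseudocount of 0.1 (SCUBE1, CPA4, SLCO2B1 and XIRP2), the replicate block (SCUBE1, SLCO2B1, XIRP2, CBLN2, AURKA and PRKCA), the calibrated table (SCUBE1, AURKA and PRKCA), no filter (SCUBE1), no scaling (AURKA) and quantile normalization (PRKCA). With only the groups compared they were lost for SCUBE1, SLCO2B1, XIRP2, METTL27, CBLN2, AURKA and PRKCA, and the YAPKO2 call for SHISA3.

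The trametinib response of the E2F target and mitosis genes was lower in YAPKO2 than in sgCON, with median differences of -0.93 and -0.91. A GC content trend between libraries is argued against as the whole cause, because the smaller absolute list median was 0.887 after the correction. Libraries that stand apart in the GC trend are argued against too, because it was 0.772 without the 2 named above, and the medians were -0.87 and -0.96 without YAPKO2 trametinib replicate 3 and -0.88 and -0.92 without YAPKO2 DMSO replicate 2. What remains open is a difference in growth that the knockout could bring, or a difference between cell lines that is unrelated to YAP1. The design cannot separate these, with 1 line per guide.

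The p53 target genes were lower in both knockout lines than in sgCON, with medians of -0.47 and -1.08. A GC trend is argued against as the whole cause, since the smaller absolute median after the correction was 0.443. A raised level in sgCON cannot be told apart from an effect of the knockout. The list lay 0.395 above parental cells in YAPKO1 and 0.87 above them in sgCON. A raised sgCON level could therefore account for the whole YAPKO1 difference. In YAPKO2 the list was not called against parental cells (median -0.39, camera adjusted p = 0.2), where 5 of 21 measured members rose and 11 fell. Those 11 lay lower than a raised sgCON level alone would leave them, but the culture time of the parental samples is uncertain. A biological effect of the knockout stays open and untested.

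MYCN was higher in sgCON than in parental cells (1.58) and higher in YAPKO1 (1.09) and YAPKO2 (0.38) than in sgCON. Copy number of the amplified region would raise the neighbours within it alike. The ratio of the neighbours' median change to that of MYCN was 0.021 for sgCON (0.016 to 0.026 when a neighbour is left out). That range rests only on the middle neighbours, NBAS and CYRIA, so its narrowness does not show that the neighbours agree. The low ratio argues against copy number, with DDX1 at -0.22 ± 0.22, NBAS at 0.025 ± 0.071 and CYRIA at 0.04 ± 0.29. The antisense gene MYCNOS did rise, by 0.63 ± 0.19 (limma adjusted p = 0.0351). Whether each neighbour lies in the amplified region was not tested. For YAPKO1 the ratio was 0.226 (0.136 to 0.317) and for YAPKO2 1.384 (0.412 to 2.356). Copy number cannot be told apart there, as the neighbours differ from each other. The median over chromosome 2, which holds MYCN, was -0.03 in YAPKO1 and -0.21 in YAPKO2 against sgCON. The ranges were added after the values were seen, the neighbours include an antisense gene and a gene near the floor, and no biological explanation was tested.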

How the results depend on the processing

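The GC correction, its form with the replicate block and the fit without 2 libraries (YAPKO1 DMSO replicate 3 and YAPKO2 trametinib replicate 2) were chosen after seeing the data, as was splitting the sgCON libraries. Same-numbered replicates did not pair, and the cause of a change was not tested. Of the named gene calls 355 were lost over the fits that leave out a library (2 to 33 each), and of the list calls 69 (0 to 8 each). No scaling moved the median of all genes by over 0.1 (log2). Estimated relative depth correlated with the number of genes above 0 (Spearman rho 0.870 over 21 libraries) and not positively with that of genes at an FPKM of 1 or more (-0.512). What absolute depth limits was not tested.

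With an estimated correlation 48 list calls held. The ribosomal protein list in YAPKO2 against sgCON in DMSO, higher at first, changed the direction of its test with quantile normalization, at a median of 0.025 and an adjusted p of 0.901 from limma's camera. A change of at least 2-fold left 546 (YAPKO1) and 1351 (YAPKO2) genes against sgCON in DMSO, 669 and 1853 in trametinib, 264 (sgCON), 323 (YAPKO1) and 629 (YAPKO2) with trametinib, 350 for the response difference of YAPKO2, 584 for sgCON against parental and 346 for YAPKO2 against YAPKO1. The response difference of YAPKO1 gave 24 genes with a pseudocount of 0.1, 23 with the calibrated table and 18 with the replicate block, where no other count was moved by over 1.5 times. Correlations of the trametinib responses (sgCON with YAPKO1, sgCON with YAPKO2, and the knockout lines) were 0.315, 0.283 and 0.397 with a pseudocount of 0.1, and 0.331, 0.286 and 0.423 with no filter. The correlation of sgCON with YAPKO1 was 0.463 with a pseudocount of 1. With the sgCON libraries split 1 and 2 between the knockout lines, the correlation of their changes was 0.518 in DMSO and in trametinib.

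The GC correction gave 3030 genes in YAPKO1 in DMSO, 1518 and 2183 with trametinib in sgCON and YAPKO1, 137 and 1609 for the response differences, 3911 for sgCON against parental, 1833 for YAPKO2 against YAPKO1 and 2112 shared in DMSO. With the replicate block as well there were 1390 and 2031 genes with trametinib in sgCON and YAPKO1, and 97 and 1456 for the response differences. Without the 2 libraries there were 3925 genes for YAPKO1 in trametinib, 1335 (sgCON) and 2847 (YAPKO1) with trametinib, 87 for the response difference of YAPKO1 and 2536 for YAPKO2 against YAPKO1, and the correlations were 0.599 (knockouts in DMSO) and 0.314 (responses of the knockout lines). With only the groups compared there were 821 genes for YAPKO1 in DMSO, 2789 for YAPKO2 in trametinib, 2674, 263 and 831 with trametinib in sgCON, YAPKO1 and YAPKO2, 8 and 445 for the response differences, 4934 for sgCON against parental and 382 for YAPKO2 against YAPKO1. The share of higher calls in the response difference of YAPKO1 (80.0%) was 66.7% with a pseudocount of 0.1, without the 2 libraries or without YAPKO1 trametinib replicate 1, 52.6% with the GC correction, 55.7% with the block as well and 62.5% with only the groups compared.

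Leaving out each library in turn gave these lowest and highest values. In DMSO YAPKO1 gave 1205 to 2136 genes, YAPKO2 2599 to 3856, and shared calls 866 to 1535 (correlation 0.597 to 0.737). In trametinib YAPKO1 gave 1419 to 2150, YAPKO2 4224 to 7914, and shared calls 1099 to 2588 (0.666 to 0.735). Trametinib gave 479 to 546 in sgCON, 752 to 1612 in YAPKO1 and 2273 to 4556 in YAPKO2. The response difference gave 12 to 40 in YAPKO1 and 506 to 1148 in YAPKO2. The counts of 7914, 4556 and 1148 are without YAPKO2 trametinib replicate 3. sgCON against parental gave 1672 to 1854, and YAPKO2 against YAPKO1 756 to 1415. Response correlations were 0.371 to 0.399 (sgCON with YAPKO1), 0.296 to 0.369 (sgCON with YAPKO2) and 0.425 to 0.507 (knockout lines). In DMSO YAPKO1 gave 1275, 1232 and 1205 without sgCON replicates 1, 2 and 3, and 1292 without its replicate 3; shared calls were 892, 866, 874 and 920. Shared calls in trametinib were 1222 and 1143 without sgCON replicates 1 and 2, and 1099 without YAPKO1 replicate 3. YAPKO2 gave a response difference of 516, 519 and 519 without sgCON DMSO replicates 1, 2 and 3, 518 and 506 without sgCON trametinib replicates 1 and 2, and 516 without its DMSO replicate 2.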

Other observations

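Comparisons with parental cells were chosen after the values were seen, and so was the choice to report the chromosome medians.

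Of the ribosomal protein genes, 21 of 35 measured members rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 change of 0.40 and a camera adjusted p of 6.84e-06 (adjusted p = 0.258 with an estimated correlation) in YAPKO2 in trametinib. For the mitochondrially encoded genes in YAPKO1 in DMSO, 0 of 13 measured members rose and 5 fell (0 and 10 adjusted over the list alone), with a median log2 change of -0.62 and a camera adjusted p of 2.60e-06 (adjusted p = 0.355 with an estimated correlation). Of the histone genes, 1 of 12 measured members rose and 6 fell (1 and 10 adjusted over the list alone), with a median log2 change of -0.67 (-0.40 without YAPKO2 trametinib replicate 3) and a camera adjusted p of 0.00118 (adjusted p = 0.459 with an estimated correlation) with trametinib in YAPKO2, a call lost without YAPKO2 trametinib replicate 3 (0.0846). Glycolysis and hypoxia genes were higher in YAPKO1 in DMSO: 10 of 25 measured members rose and 0 fell (14 and 0 adjusted over the list alone), with a median log2 change of 0.54 and a camera adjusted p of 3.41e-07 (adjusted p = 0.192 with an estimated correlation), with EGLN3, an oxygen sensor, at 1.19 ± 0.14 and the glycolytic enzyme gene ALDOC at 1.06 ± 0.17. With trametinib in YAPKO2, 3 of 25 measured members rose and 12 fell (3 and 14 adjusted over the list alone), with a median log2 change of -0.46 (-0.27 without YAPKO2 trametinib replicate 3) and a camera adjusted p of 0.00087 (adjusted p = 0.365 with an estimated correlation), and ADM, of that list, rose (2.86 ± 0.25). Of the ATF4 and unfolded protein response genes, 0 of 26 measured members rose and 6 fell (0 and 9 adjusted over the list alone), with a median log2 change of -0.22 (-0.34 without YAPKO1 DMSO replicate 1) and a camera adjusted p of 9.68e-06 (adjusted p = 0.0766 with an estimated correlation) with trametinib in YAPKO1. Of the epithelial marker genes, 0 of 5 measured members rose and 3 fell (0 and 3 adjusted over the list alone), with a median log2 change of -1.06 and a camera adjusted p of 0.00734 (adjusted p = 0.0879 with an estimated correlation) in YAPKO1 in DMSO (a call lost with no filter), with keratin KRT18, which was at 2.85 ± 0.294 in parental cells and 14.9 ± 0.712 in sgCON, at -2.58 ± 0.21 and CLDN4, a tight junction gene, at -1.20 ± 0.18. Neuronal differentiation genes with trametinib in YAPKO2 showed 11 of 23 measured members rose and 3 fell (11 and 3 adjusted over the list alone), with a median log2 change of 0.52 and a camera adjusted p of 0.00446 (adjusted p = 0.0173 with an estimated correlation), a call lost without YAPKO2 trametinib replicate 3 (0.0963). Of the BCL2 family genes, which govern cell death, 1 of 14 measured members rose and 1 fell (1 and 1 adjusted over the list alone), with a median log2 change of -0.01 and a camera adjusted p of 0.841 in sgCON with trametinib, with BMF, a promoter of death, at 0.73 ± 0.20.

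Of the Hippo pathway genes, 2 of 21 measured members rose and 7 fell (2 and 8 adjusted over the list alone), with a median log2 change of -0.22 (-0.36 without YAPKO2 trametinib replicate 3) and a camera adjusted p of 0.0404 (adjusted p = 0.11 with an estimated correlation) in YAPKO2 in trametinib, a call lost without YAPKO2 trametinib replicate 2 (0.0977) or sgCON trametinib replicate 3 (0.0678). In YAPKO1 in DMSO, 1 of 21 measured members rose and 2 fell (1 and 2 adjusted over the list alone), with a median log2 change of -0.14 and a camera adjusted p of 0.777. Lysosome and autophagy genes with trametinib in YAPKO2 showed 3 of 25 measured members rose and 2 fell (4 and 2 adjusted over the list alone), with a median log2 change of 0.14 (0.23 without YAPKO2 DMSO replicate 2, 0.07 without YAPKO2 trametinib replicate 2 and 0.23 without YAPKO2 trametinib replicate 3) and a camera adjusted p of 0.0472 (adjusted p = 0.512 with an estimated correlation), a call lost without YAPKO2 DMSO replicate 1 (0.141) or YAPKO2 trametinib replicate 2 (0.377). Receptor tyrosine kinase genes showed no called change in YAPKO1 in DMSO, where 5 of 22 measured members rose and 3 fell (8 and 3 adjusted over the list alone), with a median log2 change of 0.03 and a camera adjusted p of 0.225. The interferon response genes showed none either, where 1 of 18 measured members rose and 3 fell (2 and 4 adjusted over the list alone), with a median log2 change of -0.00 and a camera adjusted p of 0.359. The Schwann cell list gave 0 of 7 measured members rose and 0 fell (0 and 0 adjusted over the list alone), with a median log2 change of 0.02 and a camera adjusted p of 0.841 with trametinib in sgCON. The blood and endothelial list gave 0 of 3 measured members rose and 1 fell (0 and 1 adjusted over the list alone), with a median log2 change of -0.23 and a camera adjusted p of 0.158. In sgCON against parental cells the mitosis list was called, as 0 of 40 measured members rose and 4 fell (0 and 4 adjusted over the list alone), with a median log2 change of -0.15 and a camera adjusted p of 0.0287 (adjusted p = 0.302 with an estimated correlation), and the call was lost without sgCON DMSO replicate 3 (0.0807). The Hippo, lysosome and sgCON mitosis calls named here were also lost with the GC correction.

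Against parental cells YAPKO1 had 2388 genes higher and 2012 lower, and YAPKO2 3202 and 2889. The YAP/TAZ-TEAD list median was -0.54 in YAPKO1 and -0.39 in YAPKO2 against parental cells. The median over genes on chromosome 3 was -0.36 in sgCON against parental cells, on chromosome 14 it was -0.28 and on chromosome 6 it was 0.19. Against sgCON in DMSO the median on chromosome 6 was -0.24 in each knockout line. It was 0.21 on chromosome 14 in YAPKO1, and in YAPKO2 -0.21 on chromosome 2, -0.19 on chromosome 13, 0.16 on chromosome 20 and 0.23 on chromosome 22. With the GC correction the last 4 became -0.11, 0.03, 0.10 and 0.08, and the others lay between -0.31 and 0.30.

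The splits of the samples of the other comparisons into 3 against 3 number 10, too few for a share under 0.05. In each comparison no split but the real one gave as many genes. In the other splits a difference between the real groups adds to the spread within the new groups, which lowers their counts. The real counts and the highest others were 1947 and 1 (YAPKO1 in DMSO), 4373 and 1 (YAPKO2 in DMSO), 2414 and 1 (YAPKO1 in trametinib) and 5873 and 1 (YAPKO2 in trametinib). They were 837 and 0 for trametinib in sgCON, 1275 and 1 in YAPKO1 and 3242 and 2077 in YAPKO2, 2556 and 1 for sgCON against parental cells and 1125 and 1 for YAPKO2 against YAPKO1. The split with 2077 genes sets YAPKO2 DMSO replicate 2 and trametinib replicates 1 and 2 against the others, which follows the GC trend of these libraries and points to a structure of the samples. With the GC correction the real count is 4413.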
